A study of Mus musculus with 12 samples.

How the data were processed

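Gene expression was measured in male genital ridges and testes of mouse embryos on 12 Affymetrix whole-genome mouse arrays. Total RNA of each of 6 groups, which are 2 strains at 3 embryonic stages, was hybridised to 2 arrays. Per the labels, 40 pairs of testes were pooled for 2 arrays. Both arrays of a group may therefore come from the same pool, and the p-values may then measure technical spread alone.

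The deposited values hold 1 number for each of 45101 probe sets on each array. The authors do not state the summary method, the background correction, the normalization or the log base. The deposited values are taken here as log2 signal, since they run from 0 to 15 and their array medians lie between 8.1 and 8.27. The array medians differ, so the values were not quantile normalized at the level of probe sets. No array has a read depth, and the number of arrays limits the precision. The series text says that 38069 probe sets went forward in the study, without giving the rule. No raw intensities were used.

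The 64 control probe sets were left out, which left 45037 for testing. The platform annotation pairs 34945 of these 45037 probe sets with 1 gene, 932 with several genes and 9160 with none. Gene names and positions come from the RefSeq annotation of the mouse genome build GRCm38.p6, which matched 34741 probe sets and gave 18193 genes. A chromosome was known for 18032 of them. Each gene was represented by its probe set with the highest mean over the 12 arrays. A gene named with no probe set is given by this representative.

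Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with the 6 group means was fitted to the values of all 12 arrays, without a replicate block, and variances were moderated with eBayes. The fit has 6 residual degrees of freedom and 4.82 prior degrees of freedom. The 7 pairwise comparisons listed in the series text were tested, and so were the strain effect averaged over the 3 stages and the strain by stage interaction. The interaction was tested with an F test of both differences of strain effects between successive stages. All tests are two-sided, and a probe set is called at a Benjamini-Hochberg adjusted p under 0.05. Differences are M19 minus 129 or later minus earlier stage on the log2 scale, with the standard error (SE) of the model. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for annotation and plots.

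The share of chromosome 19 among called genes was tested with Fisher's exact test, and the direction of the calls with an exact binomial test. Sets of genes were tested with limma's camera at a preset inter-gene correlation of 0.01, in each of 8 comparisons, with adjustment over all 208 tests. The tests were repeated with a correlation estimated from the data. Camera then uses the 6 residual degrees of freedom, and at the preset correlation far more, so the p-values differ by more than the correlation. The 26 lists cover pluripotency, germ cell identity, the male germline piRNA pathway, meiosis, Nodal signalling, genes linked to testicular germ cell tumours, female gonad, Sertoli cells, fetal Leydig cells, cholesterol synthesis, peritubular muscle, interstitial mesenchyme, endothelium, red blood cells, macrophages, mesonephros and ducts, coelomic surface, adrenal and chromaffin cells, proliferation, cell cycle inhibitors, apoptosis, development and cancer genes of chromosome 19, oxidative phosphorylation, splicing, sex-linked genes and the 3 genes named by the study. Counts "adjusted over the list alone" come from the same fit with adjustment over the list's measured members.

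The lists, the tests described above and the rule for naming genes were fixed before the data were examined. So were the alternatives, except those named below as chosen after seeing the data. Further tests that were chosen after the results were seen are named as such where they are given. The rule takes up to 10 genes higher and 10 lower per comparison with the largest difference among called representatives. Both arrays of the higher group must lie above both arrays of the lower group, and the higher group's mean must lie above 8.17, the median of all probe set means. For the strain effect over the 3 stages, an equal sign at all 3 stages replaces the absence of overlap. List members and the genes named by the study are added.

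The procedure was tested on simulated data in which 200 of 45037 probe sets were changed between the strains at E15.5. It made 109 calls, of which 1 was false, and no call at E13.5, where nothing was changed. It recovered 3% of changes of 0.5 log2 units, 65.7% of changes of 1 unit and 93.9% of changes of 2 units. The simulated noise was independent between probe sets and arrays, with an equal spread in all groups. Unequal spread between groups, correlated genes and shared pools were therefore not covered.

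Alternatives were quantile normalization, median centring, 2 filters on dim probe sets, 2 other variance models, a replicate block, an added minimum change of 1 log2 unit, fits on the 4 compared arrays, leaving out each array in turn, averaging the arrays of a group, other probe sets of a gene and leaving out chromosome 19 genes. Settings without the E15.5 arrays, and without genes raised in 129 at E15.5, were chosen after seeing the data. Replicate numbers do not pair the arrays across groups. Over the 15 pairs of groups, the correlation of replicate differences between equal numbers ran from -0.37 to 0.54, above 0.1 in 6 pairs and below -0.1 in 7. Another pseudocount does not apply to values already on a log scale.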

Results

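Male genital ridges and testes of 129/Sv embryos (129) and of the chromosome substitution strain 129.MOLF-Chr 19 (M19) were profiled at embryonic stages E13.5, E15.5 and E17.5. M19 carries chromosome 19 of the MOLF strain on the 129 background, and its males are known to develop testicular germ cell tumours (TGCT) often. The title of the series names genes for the start and upkeep of transformed germ cells as its subject. Each strain and stage has 2 arrays, so the number of arrays limits the precision. Array medians ran from 8.1 to 8.27 on the log2 scale, and 8 to 18 probe sets per array stood at exactly 0.

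The arrays were arranged by stage before strain. The array with the highest correlation to a given array was of the same stage for 12 of 12 arrays, and of the same group for 4. Across probe sets, which are not independent replicates, Pearson's r was 0.979 to 0.996 within groups, 0.983 to 0.995 between strains at a stage, and 0.964 to 0.988 between stages. The principal components held 43.7% and 17.6% of the variance, and component 1 ordered E13.5, E15.5 and E17.5. Replicate 1 of 129 at E13.5 stood apart, at 52.3 on component 2. Its 18S rRNA control signal was 9.69, against 6.88 to 8.38 on the other arrays, and its group had the largest SD of the difference between replicates, 0.38 against 0.161 to 0.292. A tree divided into 3 clusters put that array alone, the other E13.5 arrays together, and all E15.5 and E17.5 arrays together.

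At E13.5 the strains differed in few genes, and all 6 genes called by their representatives were lower in M19. Sf1, a splicing factor that binds the intron branch point, differed by -1.94 ± 0.17 (SE, 2 arrays per strain; adjusted p = 0.0015). Lipo3, of the acid lipase family, differed by -1.69 ± 0.24, Kif20b, a mitotic kinesin, by -0.98 ± 0.13, and Kazald1, a secreted protein with a Kazal domain, by -0.83 ± 0.11; all 4 genes lie on chromosome 19. The other called genes were Morc1, which represses transposons in male germ cells, at -1.45 ± 0.16, and the germ cell RNA export factor Nxf2 at -1.36, which lies outside the naming rule at this stage because of its low signal. The male germline piRNA list, whose products silence transposons, was lower in M19 as a set. None of its 17 measured genes passed the test over all genes, and 6 were lower adjusted over the list alone, among them Piwil4 at -1.59 ± 0.28, Mael at -0.95 ± 0.15 and Dnmt3l at -0.52 ± 0.12. The set's adjusted p was 9.5e-09, and 0.091 with an estimated correlation. The fetal Leydig cell list was also lower as a set, with 0 of 14 genes called, 1 lower adjusted over the list alone (Cyp11a1, -0.58 ± 0.14), an adjusted p of 6.8e-06, and 0.033 with an estimated correlation. These sets moved in a comparison that holds the array with the high 18S signal. Without that array both sets stayed past the threshold, and without the other 129 array of this stage the Leydig list's adjusted p was 0.19.

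The E13.5 comparison called 23 of 45037 probe sets, 4 higher and 19 lower in M19. Leaving out an M19 E13.5 array gave 10 or 8 probe sets and leaving out an M19 E15.5 array gave 15 each time. A limma fit on the 4 compared arrays alone called 0, with 731 probe sets at an unadjusted p under 0.05 where chance gives 2252; the fit on all arrays had 1252. Over the 12 fits that leave out an array, Lipo3 missed the threshold in 10, Kazald1 in 9, Kif20b in 8 and Morc1 in 2, always lower in M19, and under quantile normalization the adjusted p was 0.094 for Lipo3 and 0.066 for Kazald1.

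At E15.5, pluripotency genes were higher in M19. Sox2, a transcription factor of pluripotent cells, had a mean of 10.27 in M19 (SD 0.11, n = 2) and 8.62 in 129 (SD 0.39, n = 2), a difference of 1.65 ± 0.22 (limma adjusted p = 0.0059). Dppa5a, an RNA-binding protein of pluripotent cells, was higher by 1.61 ± 0.11, the transcription factor Nanog by 1.39 ± 0.23, and the Nodal co-receptor Tdgf1 by 1.74 ± 0.33. Of the 18 measured genes of the pluripotency list, 6 were higher, the others being Dppa3 (0.82) and L1td1 (0.98). None was lower, and 10 were higher and 1 lower adjusted over the list alone. The list's median difference was 0.56 and its adjusted p 8.7e-12, or 0.091 with an estimated correlation. Other genes higher in M19 were the DNA methyltransferase Dnmt3b (1.04 ± 0.16), the translational regulator Cpeb1 (0.97 ± 0.17), the phospholipase Liph (1.04 ± 0.14), the lipid kinase Pip5k1a (0.98 ± 0.17), and on chromosome 19 Pyroxd2 (1.00 ± 0.12). Snrpd3 (1.54 ± 0.21), a core protein of the spliceosome, and Tmem258 (0.90 ± 0.16) were called by their representatives and had differences of -0.04 and -0.22 in their next brightest probe sets.

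The genes lower in M19 at E15.5 were led by genes of skin, muscle and cartilage, which were high in both 129 E15.5 arrays alone. Perp, of desmosomes, differed by -4.05 ± 0.23, the epidermal keratins Krt1, Krt5 and Krt15 by -3.65 ± 0.13, -2.93 ± 0.19 and -3.11 ± 0.16, and Krtdap, of differentiating keratinocytes, by -3.30 ± 0.19. The muscle genes Actc1 and Myh3 differed by -3.47 ± 0.13 and -2.81 ± 0.17. The cartilage collagen Col2a1 differed by -2.63 ± 0.13, and the tendon and matrix genes Tnmd and Kera by -2.70 ± 0.16 and -3.22 ± 0.14. Krt1 had a mean of 11.34 in 129 at E15.5 (SD 0.06, n = 2) and of 7.69 in M19 (SD 0.07, n = 2), and its 4 other group means lay between 7.72 and 8.01. Among list genes, Col1a1 (-0.80) of the mesenchyme list and Inhba (-0.73) of the Leydig list were lower. With Col1a1 as its called gene, the interstitial mesenchyme list was lower as a set, with 3 of 12 genes lower adjusted over the list alone, an adjusted p of 0.013, and 0.36 with an estimated correlation, or 0.065 without replicate 2 of 129 at E15.5.

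**Figure D1:**
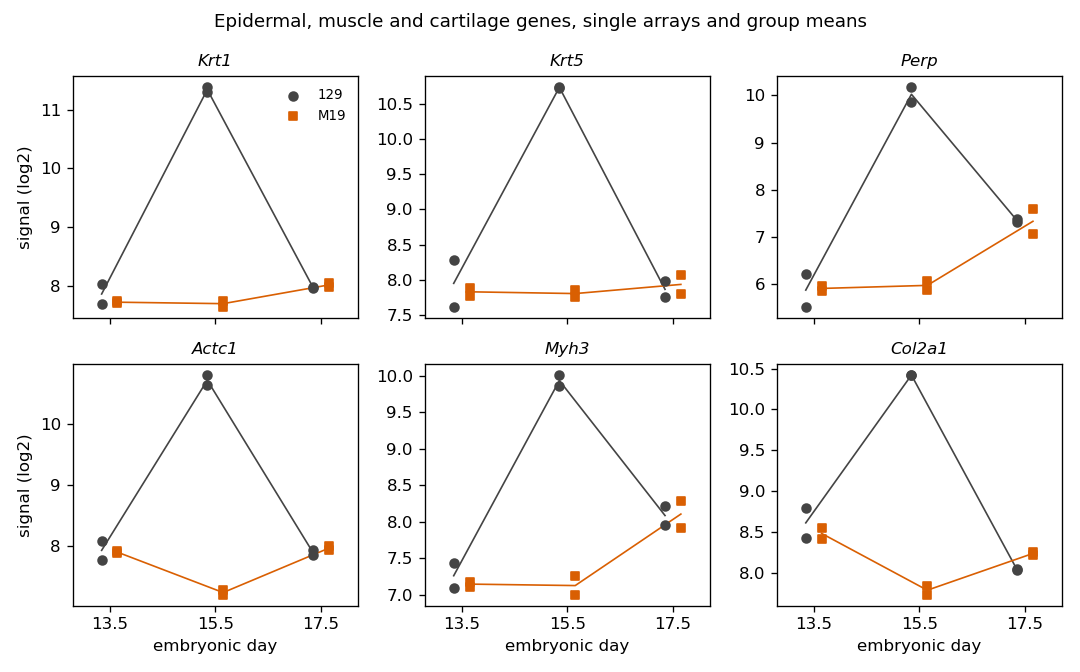
Signal of Krt1, Krt5, Perp, Actc1, Myh3 and Col2a1 (log2) against embryonic day, with points for single arrays, lines through the means of 2 arrays, grey for 129 and orange for M19. Both 129 arrays at E15.5 lie above every other array in each panel, with a Krt1 mean of 11.34 against 7.69 in M19.

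The E15.5 comparison called 258 probe sets, 54 higher and 204 lower in M19, and 124 genes by their representatives. With genes at least 1 log2 unit higher in 129 at E15.5 than at both other 129 stages left out, a setting chosen after seeing the data, 164 probe sets were called, 41 higher and 123 lower. Single arrays moved the counts: 25 higher and 143 lower (168) without either M19 E13.5 array, 14 higher and 218 lower without replicate 1 of 129 at E15.5, 35 and 90 (125) without its replicate 2, and 6 and 85 (91) and 10 and 74 (84) without replicate 1 and replicate 2 of M19 at E15.5. There were 88 higher calls without either 129 E13.5 array and 31 without either 129 E17.5 array. Nanog missed the threshold in 5 of the 12 fits that leave out an array (highest adjusted p 0.22), Sox2 in 2 (0.1), Cpeb1 in 9, Tmem258 in 8, Pip5k1a in 7, Dnmt3b and Liph in 3 each and Snrpd3 and Pyroxd2 in 1 each, with the direction kept.

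At E17.5, 10 genes were higher and 7 lower in M19 by their representatives. Otx2, a transcription factor of the epiblast and forebrain, was at 8.21 in M19 (SD 0.30, n = 2) and 6.31 in 129 (SD 0.12, n = 2), a difference of 1.89 ± 0.16 (limma adjusted p = 6e-04). Trh, the precursor of thyrotropin-releasing hormone, was higher by 1.77 ± 0.12, the endoderm factor Foxa2 by 1.10 ± 0.15, the retinoic acid hydroxylase Cyp26a1 by 0.93 ± 0.12, E-cadherin (Cdh1) by 1.47 ± 0.21, and the phosphoinositide phosphatase Mtm1 by 1.29 ± 0.16. In the pluripotency list 2 of 18 genes were higher, Tdgf1 by 2.93 ± 0.33 and L1td1 by 0.99 ± 0.14, and 6 were higher adjusted over the list alone, with an adjusted p of 5.4e-09 for the set and 0.14 with an estimated correlation. Outside the naming rule and chosen after their values were seen, a dimmer probe set of Cer1, a secreted Nodal antagonist, differed by 3.67 ± 0.15, and a dimmer probe set of the homeobox gene Lhx1 by 3.11 ± 0.33. The representatives of Cer1 and Lhx1 differed by 0.22 ± 0.17 and 0.24 ± 0.16, with an adjusted p of 1 each. In a list of 23 further genes of the early embryo 0 were called, and the median difference was 0.07.

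**Figure D2:**
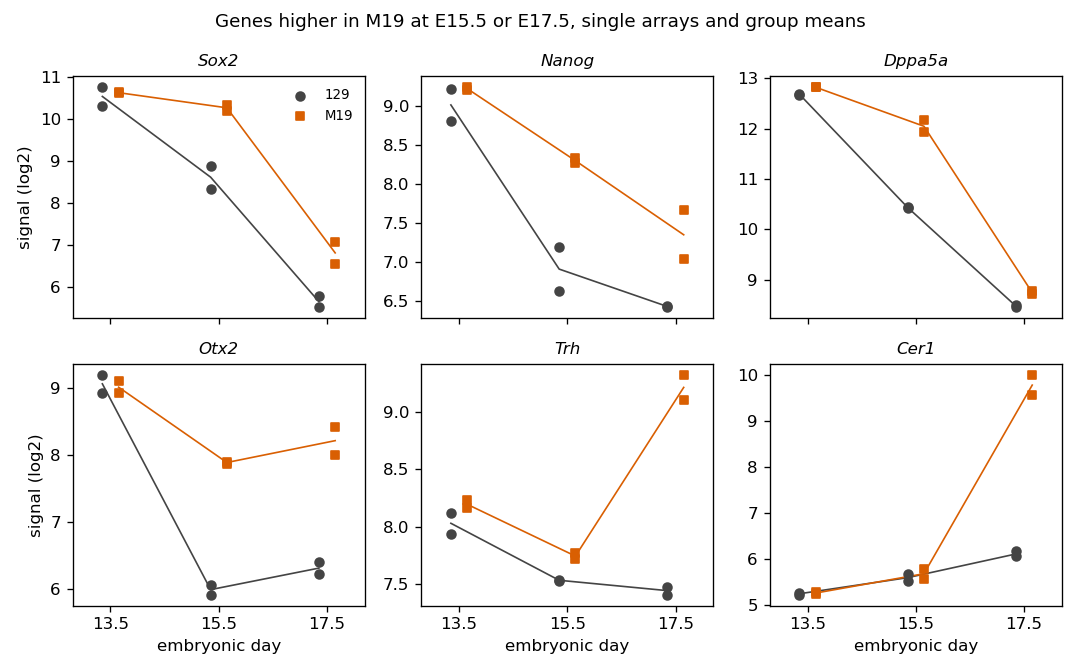
Signal of Sox2, Nanog, Dppa5a, Otx2, Trh and the dimmer probe set of Cer1 (log2) against embryonic day, with points for single arrays, lines through the means of 2 arrays, grey for 129 and orange for M19. The means of Sox2 at E15.5 are 10.27 in M19 and 8.62 in 129, and the mean of Cer1 at E17.5 is 9.78 in M19 against 6.1 in 129.

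Steroid-related sets were also higher in M19 at E17.5. The cholesterol synthesis list had a median difference of 0.24 over 16 genes with none called, and 1 gene, Dhcr7 (0.51 ± 0.11), higher adjusted over the list alone. Its adjusted p was 1e-14, and 0.027 with an estimated correlation. The adrenal and chromaffin list was higher too, with 0 of 8 genes called, a median of 0.11, an adjusted p of 0.011, and 0.3 with an estimated correlation. In the Leydig list Cyp11b1, a steroid hydroxylase also known from the adrenal, was higher by 0.87 ± 0.13, the remaining 13 genes were not called, and the adjusted p was 0.00097, or 0.065 with an estimated correlation. The mesonephros and duct list was higher with 1 of 12 genes called, Cdh1, an adjusted p of 1.7e-05, and 0.033 with an estimated correlation. The genes lower in M19 at E17.5 within the naming rule all lie on chromosome 19. They were Lipo3 (-2.09 ± 0.24), Sf1 (-2.06 ± 0.17), the aldehyde dehydrogenase Aldh1a7 (-1.39 ± 0.11), Kazald1 (-1.01 ± 0.11) and Kif20b (-1.0 ± 0.13). The E17.5 comparison called 44 probe sets, 20 higher and 24 lower, and 22 with dim probe sets filtered out. The count was 29 without either M19 E13.5 array, 14 and 16 without replicate 1 and replicate 2 of 129 at E17.5, and 15 and 21 without those of M19. Cyp11b1 missed the threshold in 10 of the 12 fits that leave out an array, Cdh1 and Foxa2 in 8 each, Cyp26a1 and Kif20b in 6 each, Mtm1 and Kazald1 in 4 each and Lipo3 in 3, with the direction kept.

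Over the 3 stages, the strain effect was concentrated on chromosome 19. Of the 84 called genes 38 lie there, or 45.2%, against 3.38% of the genes tested, with an odds ratio of 25.1 (95% interval 15.8 to 39.8, Fisher's exact p = 1.1e-33). On chromosome 19, 27 called genes were lower and 11 higher in M19 (exact binomial p = 0.014); on the other chromosomes 36 of 46 were lower. Single arrays moved these counts, with 3 higher and 18 or 16 lower of 51 or 47 called genes without replicate 1 or replicate 2 of M19 at E13.5. Without an array of 129 at E15.5 there were 5 higher and 23 or 18 lower, without 1 of M19 at E15.5 5 higher and 16 or 18 lower, without 1 of 129 at E17.5 6 and 19 or 4 and 16, and without 1 of M19 at E17.5 4 higher and 17 or 19 lower. Without replicate 2 of 129 at E13.5, with 15 higher and 28 lower, the binomial p was 0.066. The odds ratio stayed past the threshold in all 12 of these fits, at 14.7 to 24. Sf1 (-1.99 ± 0.10), Lipo3 (-1.70 ± 0.14) and Kazald1 (-0.92 ± 0.06) were called at each of the 3 stages by their representatives, and no other representative was. Dimmer probe sets of other genes were also called at each stage, among them 1 of Pum3 (-1.64, -1.54 and -1.82), 1 of Ndufv1 and 2 of Snhg1, all lower in M19, and 1 of Ric1, higher in M19. Further chromosome 19 genes lower in M19 were Aldh1a7 (-1.09 ± 0.07), Anxa1, a phospholipid-binding protein (-1.0 ± 0.08), whose difference was -0.19, -1.94 and -0.87 by stage (adjusted p of the interaction 0.0088), the telomere protein Stn1 (-0.91 ± 0.11), Kif20b (-0.88 ± 0.08), Cyp2c55 (-0.71 ± 0.09) and the ribosome biogenesis factor Rrp12 (-0.68 ± 0.09). Higher in M19 were Tmem258 (0.91 ± 0.09), Pyroxd2 (0.86 ± 0.07) and Ric1 (0.64 ± 0.10). Probe sets of the same gene often differed: the next brightest probe sets gave -0.02 for Anxa1, -0.12 for Stn1, -0.17 for Kif20b, 0.01 for Pyroxd2 and -0.13 for Tmem258. Others agreed, with -1.43 for Lipa, -0.89 for Vps37c and -0.76 for Fads2. A further probe set, not called, gave -0.02 for Lipa and -0.35 for Fads2. Of 24 other probe sets of the genes lower in M19, 83.3% were lower as well, 6 were called lower and 0 higher. In 2 further, dim probe sets of Kif20b the differences were 0.60 and 0.64, in the opposite direction (adjusted p = 0.43 and 0.34), and Ric1 had 1.31 in its next brightest probe set. By stage, 4 of 6, 19 of 124 and 9 of 17 called genes lay on chromosome 19.

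**Figure D3:**
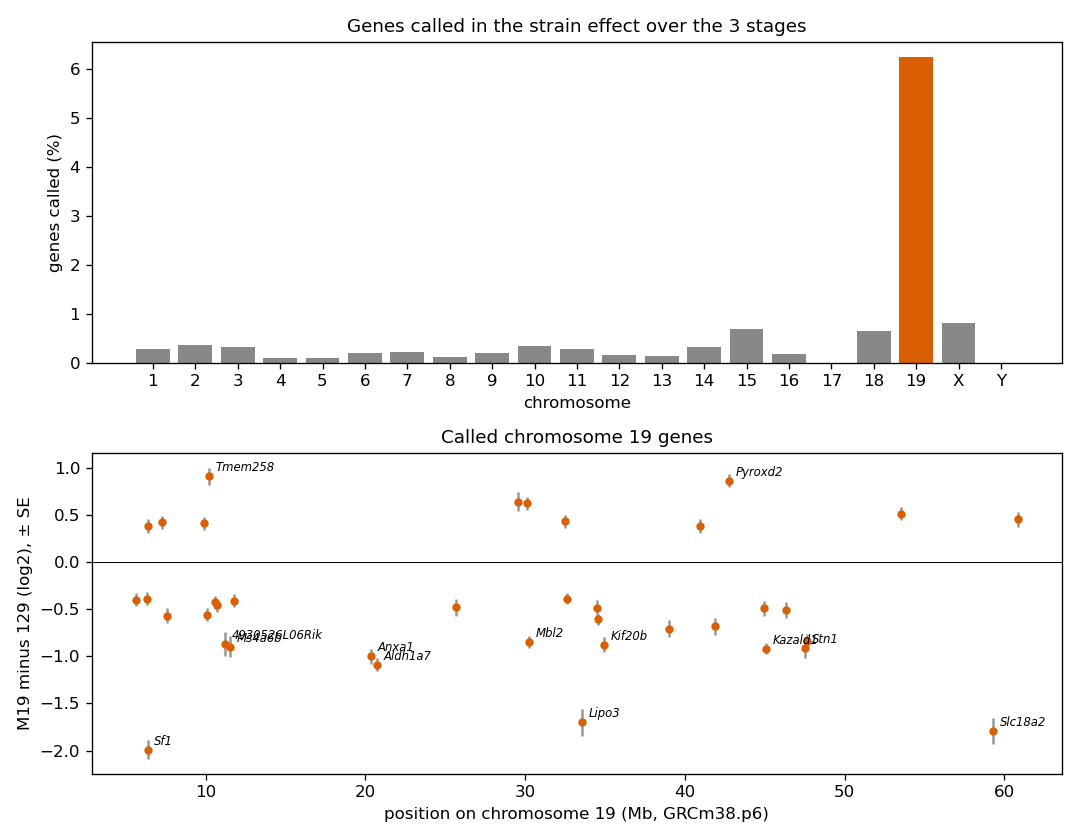
Top, percent of tested genes called in the strain effect over the 3 stages per chromosome, with chromosome 19 in orange at 6.24%. Bottom, difference between the strains (log2, M19 minus 129, bars for the SE) of the 38 called chromosome 19 genes against position in megabases, with 27 points below 0 and 11 above.

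Off chromosome 19 and within the naming rule, the genes highest in M19 over the 3 stages were Sox2 (0.97 ± 0.13), Nanog (0.84 ± 0.13), L1td1 (0.84 ± 0.08), Dnmt3b (0.73 ± 0.09), Mtm1 (0.72 ± 0.09), Trh (0.71 ± 0.07) and Dppa5a (0.67 ± 0.07). Outside the rule, Tdgf1 (1.84 ± 0.19) and Otx2 (1.24) were higher still. With Tdgf1, 5 of the 18 pluripotency genes were higher, and 8 adjusted over the list alone. The adjusted p of the set was 8e-15, and 0.065 with an estimated correlation. Egfl6, a secreted matrix protein encoded on chromosome X, was lower by -0.72 ± 0.13, with an adjusted p of 0.06 under quantile normalization. Egfl6 missed the threshold in 9 of the 12 fits that leave out an array, Ric1 in 8 and Nanog in 6. In the list of 15 measured genes linked to TGCT, among them Dnd1 and Kitl, none was called in any strain comparison or adjusted over the list alone, and the set's adjusted p was 0.48, 0.48 and 0.58 by stage and 0.99 over the stages. In the list of chromosome 19 development and cancer genes, Men1 (-0.39), Rela (-0.40) and Dmrt2 (-0.48) of 21 were lower, and 3 were higher and 7 lower adjusted over the list alone, with an adjusted p of 0.0049 and 0.15 with an estimated correlation. The adjusted p was also 0.15 without replicate 2 of 129 at E13.5, 0.066 with the mean of all probe sets per gene and 0.082 without the E15.5 arrays. Dmrt2 differed by -0.11, -0.99 and -0.33 by stage, with an adjusted p of 0.61 for the interaction. The strain effect over the stages called 189 probe sets, 52 higher and 137 lower. It called 34 without the E15.5 arrays, which hold the skin and muscle genes, in a setting chosen after seeing the data, and 8 of 10 genes then lay on chromosome 19. It called 104 and 92 without replicate 1 and replicate 2 of M19 at E13.5, 108 and 107 without those of M19 at E15.5, 115 and 110 without those of 129 at E17.5, 120 and 124 without those of M19 at E17.5, and 56 with the arrays of each group averaged.

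The study names Sf1 (as Zfp162), Pum3 (as D19Bwg1357e) and Cox15 as lower in M19 in these arrays, so their direction here is not independent evidence. Sf1 lies at 6363673 to 6378038 on chromosome 19. The brightest probe set of Sf1 was at 13.65 in 129 and 11.71 in M19 at E13.5, another differed by -0.91 over the stages, and the other 3 probe sets differed by -0.02 to -0.17. Pum3, an RNA-binding Pumilio-like protein at 27388698 to 27429908, differed by -1.67 ± 0.06 (adjusted p = 9.4e-07) and by -0.54 ± 0.06 in 2 probe sets, and its brightest probe set differed by 0.00 ± 0.06. Cox15, a haem A synthase at 43733254 to 43753000, differed by -1.32 ± 0.15 in 1 probe set (adjusted p = 0.002), and its other 3 probe sets differed by -0.07 to -0.25. As a set, with Sf1 as the 1 called gene of 3, the genes had an adjusted p of 8.5e-05, and 0.091 with an estimated correlation.

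The strain effect differed between stages for 66 probe sets, 37 of them representatives. Of these probe sets, 39 were at least 1 log2 unit higher in 129 at E15.5 than at both other 129 stages, with Krt1 and Actc1 (adjusted p = 1.9e-05 each) at the top. Dppa5a differed between strains by 0.14, 1.61 and 0.27 at the successive stages (adjusted p = 0.0046), Otx2 by -0.05, 1.89 and 1.89 (0.0049), Trh by 0.16, 0.21 and 1.77 (0.0028) and Morc1 by -1.45, 0.07 and 0.22 (0.021). For Sox2 and Nanog the adjusted p was 0.33 and 0.92, so a change of their strain effect between stages was not shown. The count was 35 and 37 without replicate 1 and replicate 2 of M19 at E13.5, 38 without replicate 2 of 129 at E15.5, 36 and 27 without those of M19 at E15.5, and 39 without either 129 E17.5 array. With dim probe sets filtered out it was 23.

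From E13.5 to E15.5 in 129, genes of the male germline programme rose and pluripotency genes fell. The piRNA factor Piwil4 rose by 4.21 ± 0.28, Tdrd9 by 3.28 ± 0.12, Nxf2 by 3.54 ± 0.12 and Morc1 by 3.27 ± 0.16. In the piRNA list 11 of 17 genes rose and none fell, with the same numbers adjusted over the list alone, and further members were Dnmt3l (2.85 ± 0.12), a cofactor of DNA methylation, and Mael (2.55 ± 0.15). In the pluripotency list 9 of 18 fell and 2 rose, also adjusted over the list alone. Falls were largest for L1td1 (-3.77), Tdgf1 (-3.45), Dppa5a (-2.25) and Nanog (-2.10), while Dppa4 rose by 1.50 and Klf4 by 1.45. The sets had adjusted p of 4.4e-16 and 1.2e-05, and 0.036 and 0.23 with an estimated correlation. Other falls were Otx2 (-3.06), the transcription factor Gata2 (-2.80), Shisa3 (-3.46), Moxd1 (-2.40), Ecm1 (-2.39), Mtm1 (-2.38) and the tight junction gene Cldn8 (-2.34). Perp (4.15), Krt1 (3.49) and Krtdap (3.14), the skin genes of the 129 E15.5 arrays, rose as well, as did alpha-fetoprotein (Afp, 3.20), Tktl1 (3.04) and Gm364 (3.03).

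Somatic cell types changed at the same step in 129. In the Leydig list 11 of 14 genes rose, with 11 higher and 1 lower adjusted over the list alone, among them the cholesterol transporter Star (1.57 ± 0.15) and the steroid enzymes Cyp11a1 (1.57 ± 0.14) and Cyp17a1 (1.51 ± 0.11). In the cholesterol synthesis list 9 of 16 rose, and 13 adjusted over the list alone, with Dhcr7 (0.97 ± 0.11) the largest. Of 11 peritubular muscle genes 5 rose, and 6 adjusted over the list alone, among them Myh11 (1.58 ± 0.14) and Acta2 (0.92 ± 0.11). Mesonephros and duct genes fell in 6 of 12, and 8 adjusted over the list alone, among them Cdh16 (-2.08 ± 0.13) and Krt18 (-1.78 ± 0.12). Coelomic surface genes fell in 5 of 8, and 6 adjusted over the list alone, among them Upk3b (-1.04 ± 0.12). The adjusted p of these 5 sets was 8.7e-12, 5.7e-11, 6.7e-05, 2.5e-08 and 1.1e-05, and 0.027, 0.031, 0.042, 0.027 and 0.033 with an estimated correlation. The embryonic globins Hbb-bh1 (-3.46) and Hba-x (-2.81) fell. The step called 2072 probe sets, 1388 higher and 684 lower, 1234 (997 higher, 237 lower) and 1230 (673 and 557) without replicate 1 and replicate 2 of 129 at E15.5, and 443 on the 4 compared arrays alone.

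From E13.5 to E15.5 in M19, the germline programme rose as well. Piwil4 rose by 5.58 ± 0.28, from a mean of 5.62 (SD 0.07, n = 2) to 11.2 (SD 0.07, n = 2). Its starting mean lay below the lower quartiles of the M19 E13.5 arrays (7.05 and 7), so the size of this rise is uncertain. Nxf2 rose by 4.83 ± 0.12, Morc1 by 4.78 ± 0.16, and Tktl1 by 4.12 ± 0.18. In the piRNA list 15 of 17 genes rose and none fell, and 16 rose adjusted over the list alone (adjusted p = 1.4e-21, and 0.031 with an estimated correlation). In the meiosis list 11 of 20 rose, and 13 adjusted over the list alone, among them Taf7l (3.39 ± 0.27), Tex12 (2.69 ± 0.18) and the synaptonemal complex gene Sycp3 (2.60 ± 0.21), with an adjusted p of 5.4e-09 and 0.048 with an estimated correlation. In 129, 7 of 20 meiosis genes rose, and 10 rose and 1 fell adjusted over the list alone, with 1.7e-05 and 0.1. In the pluripotency list 4 of 18 fell, L1td1 (-3.34), Tdgf1 (-2.56), Nanog (-0.93) and Dppa5a (-0.77), while Dppa4 (1.88) and Pou5f1 (0.79) rose. Adjusted over the list alone 7 fell and 5 rose, and the adjusted p was 0.039, or 0.57 with an estimated correlation. It was 0.055 and 0.064 without replicate 1 and replicate 2 of 129 at E13.5, and 0.063 and 0.073 without replicate 2 of M19 at E13.5 and at E15.5. Other rises were Dcaf8l (4.12), Gm364 (3.99), Afp (3.87), the small GTPase Rrad (3.62), Tex13b (3.56) and Shcbp1l (3.51). Among the falls were Shisa3 (-3.46), Moxd1 (-2.83), the homeobox gene Hoxa9 (-2.70), Gata2 (-2.70), the angiotensin receptor Agtr2 (-2.65) and Cldn8 (-2.51).

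**Figure D4:**
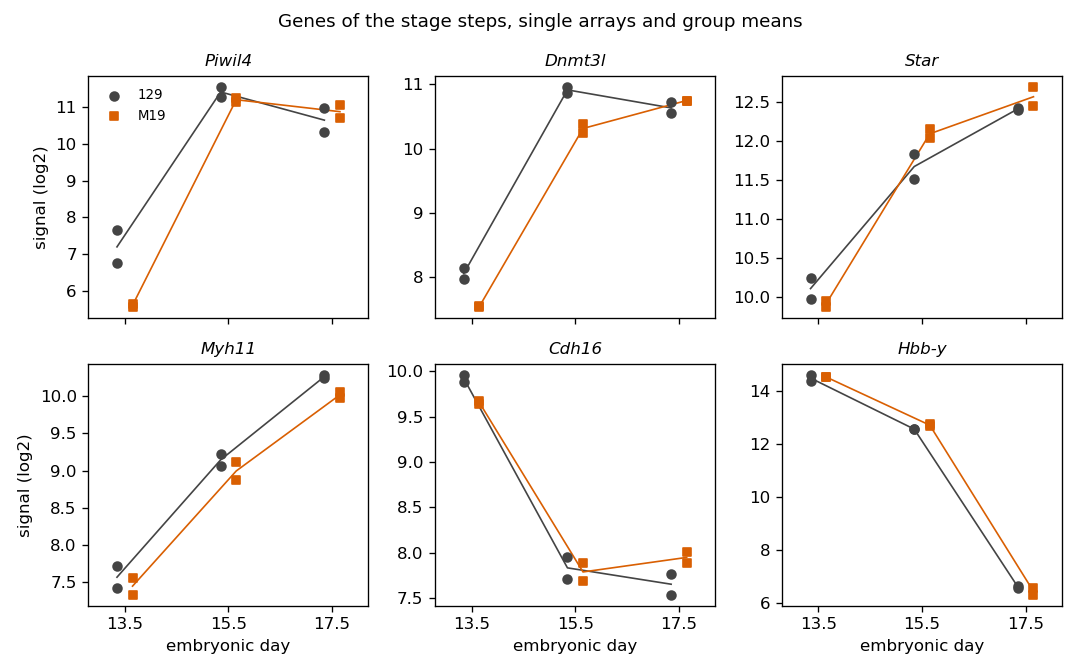
Signal of Piwil4, Dnmt3l, Star, Myh11, Cdh16 and Hbb-y (log2) against embryonic day, with points for single arrays, lines through the means of 2 arrays, grey for 129 and orange for M19. In M19 the mean of Piwil4 goes from 5.62 at E13.5 to 11.2 at E15.5, and that of Hbb-y from 14.52 at E13.5 to 6.42 at E17.5.

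The somatic lists moved in M19 at this step too. In the Leydig list 11 of 14 rose, also adjusted over the list alone, with Star at 2.19 ± 0.15 and Cyp11a1 at 2.24 ± 0.14. In the cholesterol list 11 of 16 rose, and 16 adjusted over the list alone. Of the peritubular muscle genes 6 of 11 rose, also adjusted over the list alone. In the mesonephros and duct list 7 of 12 fell, also adjusted over the list alone, among them Calb1 (-2.69) and Krt18 (-1.90), and in the coelomic surface list 3 of 8 fell, and 5 adjusted over the list alone. The adjusted p of these 5 sets was 6.1e-13, 9e-14, 0.00013, 4.5e-10 and 3.1e-06, and 0.027, 0.027, 0.047, 0.027 and 0.033 with an estimated correlation. The strains shared 624 genes that rose and 183 that fell, against 46.58 and 5.56 from chance, and 4 genes changed in opposite directions. Pearson's r of the step between the strains was 0.77 across genes, which are not independent replicates. The step called 2461 probe sets, 1745 higher and 716 lower. It called 979 and 938 without replicate 1 and replicate 2 of M19 at E13.5, 1007 and 1291 without those of M19 at E15.5, and 5549 on the 4 compared arrays alone.

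From E15.5 to E17.5 in 129, pluripotency genes and embryonic globins fell and smooth muscle genes rose. The falls were -2.96 for Sox2, -2.51 for Dppa3, -1.97 for Dppa5a and -1.51 for Pou5f1, which encodes OCT4. In the pluripotency list 7 of 18 fell and none rose, and 10 fell and 1 rose adjusted over the list alone (adjusted p = 1.6e-11, and 0.094 with an estimated correlation). Hbb-y, an embryonic beta globin, changed by -5.96 from a mean of 12.55 (SD 0.01, n = 2), and 5 of 11 red blood cell genes fell, with 5 lower and 1 higher adjusted over the list alone (adjusted p = 1.6e-05, and 0.047 with an estimated correlation). In the peritubular muscle list 4 of 11 rose, and 7 adjusted over the list alone, among them Myh11 (1.12 ± 0.14) and Tagln (1.04 ± 0.11), with an adjusted p of 5.3e-07 and 0.031 with an estimated correlation. Other rises were the cystatin Cst12 (3.06 ± 0.16), Ccdc113 (2.70), the protease inhibitor Serpina5 (2.12), the chemokine Ccl17 (1.67), the imprinted noncoding RNA Rian (1.65), Adamts5 (1.64), Islr2 (1.50), the fibulin Efemp1 (1.45), the basement membrane collagen Col4a4 (1.40) and Igfbp6 (1.39). The skin and muscle genes of the 129 E15.5 arrays fell, with Krt1 at -3.38, Krtdap at -3.29, Kera at -3.27, Krt15 at -3.01, Krt5 at -2.87 and Actc1 at -2.82, and so did Cdh1 (-2.74). Hoxa10 (-2.90) was called by its representative and differed by 0.18 in its next brightest probe set. The step called 777 probe sets, 375 higher and 402 lower, and 429 on the 4 compared arrays alone. It called 1277 without either 129 E13.5 array, 469 without either M19 E13.5 array, 411 (99 higher, 312 lower) and 376 (209 and 167) without replicate 1 and replicate 2 of 129 at E15.5, and 298 (133 and 165) and 218 (65 and 153) without those of 129 at E17.5, so which direction had more calls depended on single arrays. Efemp1 missed the threshold in 7 of the 12 fits that leave out an array, Rian in 3 and Islr2 in 2.

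From E15.5 to E17.5 in M19, Hbb-y fell (-6.28) and so did pluripotency genes. The falls were -3.45 for Sox2, -3.43 for Dppa3, -3.31 for Dppa5a and -2.27 for Lin28a, an RNA-binding protein of immature germ cells, whereas Tdgf1 rose by 1.93. In the pluripotency list 9 of 18 fell and 1 rose, and 12 fell and 2 rose adjusted over the list alone (adjusted p = 5.9e-12, and 0.091 with an estimated correlation). In the peritubular muscle list 5 of 11 rose, and 8 adjusted over the list alone (4.2e-07, and 0.031 with an estimated correlation). In the Leydig list 4 of 14 rose, Inhba by 0.77, Dlk1 by 0.70, Scarb1 by 0.57 and Cyp17a1 by 0.48, and 8 adjusted over the list alone (7.5e-06, and 0.033 with an estimated correlation). In 129, Star (0.74) was the called Leydig gene, with 5 higher and 1 lower adjusted over the list alone (0.00017, and 0.047 with an estimated correlation). Of the red blood cell genes 4 of 11 fell, with Hba-x at -3.15, and Alas2, of haem synthesis, rose by 0.76; adjusted over the list alone 6 fell and 2 rose (0.00016, and 0.065 with an estimated correlation). Other rises were Cst12 (2.61), Serpina5 (2.17), Ccl17 (1.76), Adamts5 (1.75), the histone demethylase Kdm1b (1.55), proenkephalin (Penk, 1.48), Trh (1.47), Spock2 (1.45), Stfa2l1 (1.40) and Ogn (1.32), and other falls were Glis3 (-2.45), Gm6958 (-2.19), Hmga2 (-2.05) and Liph (-1.93). The strains shared 129 genes that rose and 114 that fell, against 3.09 and 4.04 from chance, and 6 changed in opposite directions. Pearson's r across genes was 0.59. The step called 1052 probe sets, 445 higher and 607 lower. It called 1896 without either 129 E13.5 array, 551 without either M19 E13.5 array, 173 (100 higher, 73 lower) and 288 (96 and 192) without replicate 1 and replicate 2 of M19 at E15.5, and 269 (151 and 118) and 356 (113 and 243) without those of M19 at E17.5. Lin28a missed the threshold in 2 of the 12 fits that leave out an array and Kdm1b in 1.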

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

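The tests on a fault of a 129 E15.5 array, on the gonad at E15.5, on a larger share of germ cells, on a lag of germ cells alone, on E17.5 genes above other groups and on probe mismatch were chosen after the results were seen, and Cer1 was chosen after its values were seen. The tests on other tissue and on early embryo genes used gene sets that had not been looked at. The test on slower development at E15.5 was written before its result was seen, but its genes were chosen by their change with stage on these arrays. The slopes at E13.5 and E17.5 were not part of that prediction. All slopes were compared with few other splits of the arrays, so a lowest slope carries little weight.

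The strain effect of 66 probe sets differed between stages in limma's interaction test. In the named genes, the strain effect at E15.5 minus that at E13.5 was 1.52 for Morc1, 1.48 for Dppa5a, 1.93 for Otx2, 1.29 for Nxf2, -1.76 for Anxa1 and -4.09 for Perp. The strain effect at E17.5 minus that at E15.5 was 3.7 for Krt1, 3.54 for Actc1, 3.38 for Krtdap, 3.33 for Kera, 3.19 for Krt15, 3 for Krt5, 2.83 for Myh3, 2.84 for Col2a1, 2.59 for Tnmd, 1.56 for Trh and 3.58 for the dimmer probe set of Cer1.

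Skin, muscle and cartilage genes were high in 129 at E15.5 alone. A fault of a lone array was excluded as the whole cause, since the median of 66 further markers lay 0.191 and 0.143 above the other 129 stages on the 2 arrays, against -0.107 on both M19 E15.5 arrays. Tissue other than the gonad in the 129 E15.5 pool may account for the pattern: the medians of all 3 lists of unseen markers, epidermis (-0.25, 27 genes, 7 of them called lower in M19), skeletal muscle (-0.20, 24 genes, 3 called) and cartilage and bone (-0.24, 15 genes, 1 called), lay below the 2.5th percentiles of random lists, which were -0.07, -0.10 and -0.10. The most abundant called markers were Dsp at 10.75 in 129 and 9.67 in M19, Sbsn at 10.02 and 8.84, and Krt4 at 9.98 and 8.92, and 15, 6 and 9 markers of the lists exceeded the median signal in the other 5 groups as well. A strain difference in the gonad at E15.5 stays open: at E17.5 the median effect over all markers was 0.02, but that of cartilage and bone was -0.07, below the 2.5th percentile of random lists (-0.05), and with what may be 1 pool per group, pool and strain cannot be told apart.

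Sox2, Dppa5a and Nanog were higher in M19 at E15.5, and Trh, Foxa2, Cyp26a1 and a dimmer probe set of Cer1 at E17.5. A larger share of germ cells alone would raise other germ cell genes by about as much. The median strain effect at E15.5 was 0.18 ± 0.11 for 17 germ cell genes outside the pluripotency list, against 0.56 for its 18 genes. At E17.5 the germ cell genes had a median of 0.02 ± 0.05. These values argue against a larger share as the whole cause. A lag of germ cells alone predicted lower values in M19 for 28 germ cell genes that rise from E13.5 to E15.5. Their median at E15.5 was 0.23 ± 0.08, but at E13.5 it was -0.30, with 0 of 28 above 0. The test cannot exclude a lag, since other tissue in the 129 E15.5 pool would also lower the germ cell signal in 129. A lag and a larger share together stay open as well. Each SE here is that of a median over genes, which are not independent replicates. It leaves out the spread between arrays and pools. Slower development of M19 may contribute at E15.5: over 4741 genes of other kinds that change between E13.5 and E17.5, the slope of the strain effect on that change was -0.053, below both other splits of the 4 arrays (-0.003 and 0.02), as it was at E13.5 on the earlier step (-0.116, against -0.026 and -0.028) and at E17.5 on the later step (-0.078, against 0.007 and -0.03), though over both steps it was -0.016 at E17.5 (against 0 and -0.011), and the slope of the pluripotency genes was -0.403, so a lag of the whole gonad of that size would leave most of their difference. At E17.5 an earlier stage does not account for Trh, Foxa2 and Cyp26a1, the 3 of 10 genes called higher that stood above every other group by more than 2 SE, but for the other 7, among them Otx2 (8.21 in M19, against 9.05 in 129 at E13.5), this test does not exclude it. Cells like those of the early embryo in the M19 E17.5 pool are a candidate explanation that stays open: 23 unseen epiblast, streak and endoderm genes had a median strain effect of 0.07, at percentile 98.2 of random lists, with 0 of 23 called and Gata6 (10.24 in M19, 10.19 in 129) and Grhl2 (10.17 and 10.21) the most abundant, 12 of the genes also exceeded the median signal in the other groups, and a pool difference cannot be separated from a strain difference.

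Chromosome 19 held 38 of the 84 genes called between the strains. A mismatch between MOLF sequence and the probes lowers signal, so by this premise it cannot produce the 11 calls higher in M19. Their odds ratio on chromosome 19 was 32 (95% interval 12.3 to 84.4, Fisher's exact p = 1.5e-11). The lowest of the fits that leave out an array was 10.8 (1.84 to 45), without either M19 E13.5 array. These odds ratios show a concentration of the higher calls on chromosome 19 and do not test the premise. A mismatch to the 129 sequence would raise these genes in M19 and may account for part of them: in 5 of the 11 genes the slope of 10 other probe sets on the representative was 0.24 (-0.15 to 0.89), an interval that holds both 0 and 0.51. For the 27 genes lower in M19 a mismatch may account for part of the calls. In 13 genes with other probe sets, the slope of those 24 probe sets on the representative was 0.2 (0.02 to 0.68). For genes of the E13.5 to E15.5 step in M19 it was 0.51 (0.46 to 0.56). Of the 24 probe sets 83.3% shared the representative's sign, against 84.6%, and 6 were called lower and 0 higher. The slope weights a gene by its representative's squared difference, so Sf1 (-1.99) weighs most. Other probe sets of Sf1 had -0.91, -0.17, -0.15 and -0.02. Those of Kif20b (-0.88) had -0.17, 0.60 and 0.64. The low slope may thus rest on few genes, and none was computed without Sf1 and Kif20b. For genes called in the same strain effect on other chromosomes, the slope was 0.69 (0.38 to 1.09) over 8 other probe sets of 6 genes. All of these, 100%, shared the sign. This interval overlaps that of the lower chromosome 19 genes, 0.02 to 0.68, which leaves lower expression and probe mismatch open. For these 27 genes they cannot be told apart without the MOLF sequence, which was not used here.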

How the results depend on the processing

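The E15.5 and raised-gene exclusions were chosen after seeing the data; all other alternatives were chosen before. Quantile normalization, median centring, the 38069 brightest probe sets, trended or robust variances and the replicate block kept all 9 counts of probe sets within 1.5 times. With the block, the counts were 24, 276 and 44 for the strain effects by stage, 2055 and 742 for the 129 steps, 2492 and 1014 for the M19 steps, 190 over the stages and 65 for the interaction, the chromosome 19 odds ratio was 25.8, and 81 of 82 set calls and 137 of 138 named results stayed past the threshold. The odds ratio ran from 14.4 to 235 over the other settings, always past the threshold. All 12 arrays had their nearest array at the same stage under each setting tried. With probe sets above the median level, which tests fewer probe sets, counts were 150 at E15.5, 22 at E17.5, 120 over the stages and 23 for the interaction. With at least 1 log2 unit, which can only drop calls, they were 147 at E15.5, 664 and 249 for the 129 steps, 731 and 254 for the M19 steps and 40 over the stages. On the 4 compared arrays alone they were 0 at E13.5, 443 and 429 for the 129 steps and 5549 for the E13.5 to E15.5 step in M19. The fit on all 12 arrays assumes an equal spread in all groups. The SD of the difference between replicates was 0.161 and 0.212 in M19 at E13.5 and E15.5. In 129 it was 0.38 and 0.292 at these stages. Whether unequal spread accounts for these counts was not tested. Averaged arrays gave 56, from fewer samples, and leaving out chromosome 19 genes 65. Without E15.5 arrays 34 probe sets were called over the stages, and without genes raised in 129 at E15.5, 164 at E15.5, all among the 258. Loss of the raised genes is by construction, but calls higher in M19 also went from 54 to 41. Leaving out many low p-values makes the Benjamini-Hochberg cut-off stricter for the rest, which can lower this count. Its share was not separated from that of the refitted variances.

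Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 8 to 32 at E13.5, 84 to 351 at E15.5, 14 to 52 at E17.5, 1230 to 2739 and 218 to 1277 for the 129 steps, 938 to 3242 and 173 to 1896 for the M19 steps, 92 to 251 over the stages and 27 to 90 for the interaction. These fits made 68 to 84 set calls, of which 65 to 81 were among the 82, and the pluripotency list at E13.5 had medians of -0.04, without replicate 1 of 129 at E13.5, to 0.14. With an estimated correlation 23 of 82 set calls remained. A higher correlation was not the cause in every list. The peritubular list at E13.5 had an estimate of -0.037, below the preset 0.01. Its adjusted camera p still went from 0.011 to 0.12. The Leydig list at E13.5 had an estimate of 0.003, and its unadjusted camera p went from 8.2e-07 to 0.0021. Other lists had estimates above the preset, such as 0.264 for pluripotency. With an estimated correlation, camera also refers its statistic to the 6 residual degrees of freedom of the fit, and at a preset correlation to far more. A set's p-value can therefore rise without a higher correlation. In next brightest probe sets, 29 of 49 named results stayed past the threshold with the same sign, and 4 turned: Snrpd3 -0.04 and Tmem258 -0.22 at E15.5, Tmem258 -0.13 over the stages and Hoxa10 0.18 in the later 129 step; the cause was not tested. Signals near background limit dim genes, which the simulated data did not cover separately.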

Other observations

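Supporting cells and vessels also changed with stage. From E13.5 to E15.5, 5 of 22 Sertoli genes rose and 3 fell in 129, and 9 rose and 3 fell in M19, with Inha (1.40 and 1.50) and the chaperone Clu (0.99 and 1.13) rising and Fgf9 (-0.90 and -1.21) and Cldn11 (-0.94 and -0.78) falling in both strains. The adjusted p of the set was 0.0097 and 0.00093, or 0.42 and 0.3 with an estimated correlation; in 129 it was 0.36 without replicate 1 at E13.5. In the endothelial list 3 of 12 genes fell in each strain, Kdr (-0.90 and -0.76), Emcn (-1.23 and -1.16) and Cldn5 (-0.52 and -0.71), with the set called in both (adjusted p = 0.0082 and 0.00038, or 0.26 and 0.14 with an estimated correlation). In the Nodal list 3 of 9 fell in 129 and 4 in M19, among them Lefty1 at -0.89 in both strains (0.011 and 0.0039, or 0.12 and 0.091). Without replicate 2 of 129 at E13.5 the adjusted p in 129 was 0.21 for the endothelial and 0.059 for the Nodal list. Over the stages the Nodal list was higher in M19, with Tdgf1 (1.84) as its called gene of 9 (0.00016, and 0.047 with an estimated correlation). Of the female gonad list Sohlh1, a transcription factor that spermatogonia also use, rose by 2.82 in 129 and 3.08 in M19, while Wnt4 fell (-0.67 and -0.44), and the set's adjusted p was 0.74 and 0.98. Among cell cycle inhibitors Cdkn2a rose by 0.85 and 1.16 and Cdkn1a fell (-0.67 and -0.66) (0.98 and 0.92 for the set). Cyp21a1, a steroid 21-hydroxylase of the adrenal list, rose by 0.73 and 1.07 (0.72 and 0.54 for the set).

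From E15.5 to E17.5 germ cell genes fell as sets. Of 18 germ cell identity genes 5 fell in 129 and 7 in M19, and 9 and 10 adjusted over the list alone (adjusted p = 6.7e-06 and 9.9e-08, or 0.2 and 0.14 with an estimated correlation). Of 17 piRNA genes 3 fell in 129, and 4 fell and 1 rose in M19 (1.4e-06 and 0.00013, or 0.14 and 0.21), and of 20 meiosis genes 3 and 5 fell (0.041 and 0.00011, or 0.39 and 0.14). The proliferation list was lower as a set at the earlier step with 0 of 21 genes called in each strain (0.00068 and 6.9e-05, or 0.39 and 0.31) and in 129 at the later step (0.0044, or 0.47, with 0.079 in M19). In M19 the later step had higher interstitial mesenchyme, with 3 of 12 genes called (0.0021, or 0.25), and macrophage lists, with 1 of 15 (0.0039, or 0.14), and lower oxidative phosphorylation (0 of 18 called, 0.0065, or 0.31), sex-linked (0 of 4, 0.018, or 0.38) and splicing lists (0 of 16, 0.04, or 0.16). In 129 these 5 lists moved in the same directions with adjusted p of 0.13, 0.22, 0.66, 0.69 and 0.065, and differences of list effects between the strains were not tested. Endothelial genes were higher at the later step, with 1 of 12 called in each strain (0.011 and 0.04, or 0.28 and 0.38), as was the Sertoli list in 129, with 2 of 22 genes rising and 1 falling (6.7e-05, or 0.22, with 0.079 in M19). The germ cell identity list was higher at the earlier step in M19, with 8 of 18 rising and 3 falling (0.011, or 0.46, with 0.35 in 129). Single arrays ended some of these calls. In 129 the adjusted p was 0.086 for proliferation at the earlier step without replicate 2 at E13.5 and 0.078 at the later step without replicate 1 at E17.5, and 0.16 for the endothelial list at the later step without replicate 2 at E17.5. For meiosis at the later step in 129 it was 0.055 and 0.064 without the arrays of 129 at E13.5, 0.083 without replicate 2 at E15.5, and 0.068, with a median of 0.07, without replicate 2 at E17.5. In M19 at the later step it was 0.052 and 0.061 for the endothelial list without the arrays of 129 at E13.5, and 0.14 and 0.15 without replicate 2 of M19 at E15.5 and at E17.5. It was 0.079 for the sex-linked list without replicate 1 at E17.5, and for splicing 0.076 without replicate 2 at E15.5 and 0.05 and 0.066 without replicate 1 and replicate 2 at E17.5.

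Further sets differed between the strains with few or no called genes. At E13.5 M19 was lower in meiosis (adjusted p = 0.0013, or 0.19 with an estimated correlation), peritubular muscle (0.011, or 0.12) and germ cell identity genes (0.032, or 0.53), and higher in Nodal (0.0025, or 0.083) and pluripotency genes (0.027, or 0.54), the last of which reversed to a median of -0.04 without replicate 1 of 129. Without replicate 2 of 129 at E13.5 the adjusted p was 0.42 for meiosis, 0.37 for peritubular muscle, 1 for germ cell identity and 0.086 for Nodal, and it was 0.12 for germ cell identity without replicate 1 and 0.075 for pluripotency without replicate 2 of M19. Over 2482 genes outside the germ cell lists that change from E13.5 to E15.5, the slope of the strain effect at E13.5 on that change was -0.116, in the direction of an earlier stage in M19, and of 28 germ cell genes that rise over this step all were lower in M19 at E13.5, with a median of -0.30. At E15.5, beside the skin and muscle genes high in 129, M19 was higher in meiosis (0.00021, or 0.14), germ cell identity (1 of 18 called, 0.0059, or 0.44), cholesterol synthesis (0.008, or 0.2), oxidative phosphorylation (0.037, or 0.45) and sex-linked genes (0.043, or 0.46), and lower in macrophage (0.0042, or 0.14) and chromosome 19 development genes (1 of 21 called, 0.0039, or 0.14). Of these, without replicate 1 of 129 at E15.5 the adjusted p was 0.11 for germ cell identity, 0.11 for oxidative phosphorylation and 0.33 for sex-linked genes. Without replicate 1 of M19 at E15.5 it was 0.086 for cholesterol synthesis, 0.33 for oxidative phosphorylation and 0.15 for sex-linked genes. It was 0.086 for oxidative phosphorylation without replicate 2 of 129 at E15.5 and 0.052 for sex-linked genes without replicate 2 of 129 at E13.5. At E17.5 M19 was higher in Nodal (1 of 9 called, 0.0014, or 0.069) and adrenal genes (0 of 8, 0.011, or 0.3) and lower in peritubular muscle genes (0 of 11, 0.042, or 0.18). The peritubular list missed the threshold in 5 of 12 fits that leave out an array, with 0.7 and 0.58 without replicate 2 of 129 and of M19 at E17.5, the latter with a median of 0.01, and 0.053 to 0.058 without replicate 2 of 129 at E13.5 or either 129 E15.5 array. For the adrenal list it was 0.1 and 0.15 without replicate 1 of 129 and of M19 at E17.5. Over the stages it was higher in cholesterol synthesis (0 of 16 called, 6.7e-06, or 0.065) and lower in peritubular muscle (0.00081, or 0.065), interstitial mesenchyme (0.0019, or 0.25) and macrophage genes (0.0031, or 0.14). Without the E15.5 arrays, a setting chosen after seeing the data, the adjusted p was 7.8e-06 for cholesterol synthesis and 0.00092 for peritubular muscle, but 0.056 for interstitial mesenchyme and 0.082 for macrophages, and without replicate 2 of 129 at E13.5 it was 0.18 for interstitial mesenchyme. The apoptosis list was not called in any comparison; over the stages 0 of 14 genes differed between strains, with an adjusted p of 0.66.

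The division of the arrays into strains was compared with other divisions within each stage, a test written before the result was seen. Of 100 divisions drawn from 108 possible, 1, the real one, reached the 189 probe sets of the strain effect over the stages. The next highest had 73 and the median of the others was 1. Most other divisions put arrays of both strains in a group, which adds strain differences to the spread and lowers the count. Divisions that kept both arrays of each group together gave 59, 45 and 49, with the strains swapped at E13.5, E15.5 and E17.5. The real count was higher, but such divisions are too few to exclude a random grouping of pools. Arrays of a shared pool are not independent, so this limits what the comparison can tell about strain as opposed to pool.

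The higher pluripotency signal in M19 at E15.5 could be a delayed loss of these genes in germ cells. Whether the germ cells are also behind in other genes stays open. Germ cell genes that rise up to E15.5 had a median of 0.23 in M19 minus 129 at E15.5, but of -0.30 at E13.5. Protein staining of single germ cells for SOX2 and NANOG in separate embryos would tell a delayed loss from a change in cell number. Testes of further 129 litters dissected at E15.5 would show whether the skin and muscle genes belong to that pool or to the strain. Sequence of MOLF chromosome 19 under the probes would separate probe mismatch from lower expression.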
